A study of Mus musculus with 6 samples.

How the data were processed

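The series holds 6 RNA-seq libraries from cancer-associated dendritic cells of tumour-bearing mice. Per the labels' protocols, total RNA was isolated with Trizol and libraries were made with the TruSeq Stranded Total RNA kit, for all 6 samples alike. The labels place 2 libraries each in the high experiment with non-targeting (NT) or Satb1 siRNA, and 1 library each in the low experiment. How the cells were sorted, and whether replicates came from separate mice, is not given in the sources used here. The names high and low are taken from the samples' labels, which state how far Satb1 was downregulated.

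A single deposited table held all values, with 27634 gene symbols and no unnamed rows. Per the file headers it holds an FPKM value and a count for each gene and library. The authors' FPKM values are relative to gene length and library size, and they were used here only for Satb1 and DQ567786. The deposited counts are taken for estimated counts (RSEM's expected counts), since RSEM 1.2.12 is named in the submitters' processing notes, together with DESeq2 and the mouse genome build mm9. The values in all 6 libraries were already whole numbers, so that rounding changed nothing. The aligner, the filters and the handling of strand are not given in the sources used here. An estimated count divides reads that fit several genes among them, so values of near-identical genes such as histones, Hspa1a and Hspa1b, or Lyz1 and Lyz2 depend on that step. No annotation of mm9 was used, and no coordinates are given. A GENCODE annotation of another mouse build served only to give a total intron length to 20785 genes.

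Total counts ran from 24553454 to 71272720 per library. A count of 0 allows up to 3 counts, or 0.0421 to 0.122 CPM. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Before groups were compared, the counts of the repeats were set against each other with a chi-square per gene, over genes with a summed count of at least 10. The repeats of a group were almost as alike as counting noise allows. They were counted as 1 sample per group in every statement about the conditions, while the planned tests, which use them as separate libraries, are given as comparisons of those libraries. The replicate numbers did not pair the samples.

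The main test was edgeR 4.0.16 in R 4.3.3, with quasi-likelihood F-tests (robust), TMM scaling, the filterByExpr filter by group, two-sided p-values and Benjamini-Hochberg adjustment with a threshold of 0.05. It was fitted to the 4 libraries of the high experiment. The low experiment has 1 library per siRNA and was described by log2 ratios of CPM with a prior count of 2 after TMM scaling over 6 libraries, for genes with a mean log2 CPM of 0 or more. A 2-fold change is 1 on the log2 scale. The Satb1 ratio of the low experiment has an exact 95% counting interval. The difference of effects between the experiments was tested in edgeR as an interaction over 4 group means. The control libraries of the experiments were compared by log2 ratios without a test. Levels of the high experiment are in CPM scaled within its own 4 libraries, except in the plot of single genes and for the levels of Satb1 and the sums of transcripts without a poly(A) tail, which are relative to the unscaled library totals unless TMM is named.

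A total of 31 gene lists (17 pathways, 14 cell types) was fixed before the data were examined, from textbook knowledge. Of 520 entries, 493 matched the file, 3 of them by an older symbol, and 27 were not analysed here. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01) on log2 CPM, and each list's median was given as a percentile of 10000 random lists of the same size drawn from 20 bins of mean expression. The gene lists share members, so their results are not independent. With a correlation estimated from the data, camera rests on the few residual degrees of freedom of 4 libraries. Loss of a call under that setting was therefore likely in advance.

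The genes to name were set by a rule fixed before the data were examined. It takes Satb1, the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 1, no overlap between the groups and no symbol of the kinds of unnamed loci and small RNA that the rule lists; DQ567786, also an unnamed locus, is of a kind not listed and was kept. It adds the 2 members of each list with the smallest p, 8 fixed genes (Il6, Lgals1, H2-Ab1, H2-Aa, Cd74, Ciita, Cd40 and Notch1) and the 10 genes with the smallest interaction p, and gave 89 genes. The genes Malat1, Neat1, Kcnq1ot1, Xist, Miat, Ccl2, Cxcl1, Cxcl13, Il1b, Nos2, Cd274, Plac8, Flt3, Zbtb46, Csf1r, Mertk, Timd4, S100a8, S100a9 and Upk3b, and those named among the shared falls, were chosen after their values were seen.

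The fits were tested on simulated counts drawn from the means and depths of the real libraries. All simulated genes had the common spread of the near-identical repeats. For the interaction all 6 libraries had the same profile and that spread too. The rates below hold only under these assumptions and do not show how many real interaction calls are false. For the high comparison, with 19677 simulated genes tested, edgeR recovered 82% of genes changed 1.2-fold, 94% at 1.5-fold and 100% at 2-fold and 4-fold, with 6 false calls. For the interaction, with 18722 genes, it recovered 28%, 62%, 94% and 94% at the same sizes, with 9 false calls. Alternatives covered scaling (DESeq2 size factors, library size alone), the tool (DESeq2 1.42.0, limma voom), filters, the threshold, replicate number as a block, fits over all 6 libraries, and leaving out each library of the high experiment. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.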

Results

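RNA was sequenced from cancer-associated dendritic cells of C57BL/6 mice carrying ID8-Defb29/Vegf-a tumours, a mouse ovarian cancer cell line engineered to express beta-defensin 29 and VEGF-A, that had grown for 32 to 38 days. The mice received nanocomplexes of 100 µg siRNA with rhodamine-labelled polyethylenimine, a polymer that carries nucleic acid into phagocytic cells. The siRNA was either non-targeting (NT) or directed at Satb1, which encodes a chromatin organiser of lymphoid and myeloid cells. The labels define 2 experiments by how far Satb1 fell. The experiment with strong downregulation (the high experiment) had 2 libraries per siRNA, and the experiment with weak downregulation (the low experiment) had 1 library per siRNA. Summed over 27634 genes, the deposited counts came to 67774712 and 71272720 in the high NT libraries and 51710612 and 49022011 in the high Satb1 siRNA libraries. They came to 27029554 in the low NT library and 24553454 in the low Satb1 siRNA library. The 2 libraries of each high group were nearly identical. Their counts gave a chi-square of 1.202 per gene for NT and 1.370 for Satb1 siRNA, where counting noise alone gives about 1, and the biological coefficient of variation in edgeR was 0.00988. Single genes differed between the repeats at 59 of 21413 genes for NT and 89 of 21409 for Satb1 siRNA, against 11757 of 21689 between an NT and a Satb1 siRNA library. The repeats therefore differed by little more than sampling noise, and each group was counted as 1 sample. Standard errors and p-values below compare the sequenced libraries and measure the spread between these repeats. Whether the repeats are independent samples is not known, so no comparison of the conditions over independent samples was made within the high experiment.

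Satb1 was lower in both Satb1 siRNA libraries of the high experiment and close to its control level in the low experiment. In the high experiment its counts were 1233 and 1193 in the NT libraries and 184 and 200 in the Satb1 siRNA libraries, or 18.2 and 16.7 against 3.56 and 4.08 CPM (counts relative to the library total). The log2 fold change was -2.25 (SE 0.072 between repeats, edgeR quasi-likelihood test, adjusted p = 1.74e-39). The authors' deposited FPKM values were 2.91 and 2.70 against 0.57 and 0.63. In the low experiment 170 counts were seen with NT siRNA and 165 with Satb1 siRNA. After TMM scaling the ratio was 0.835, with a 95% counting interval of 0.670 to 1.04, so a fall was not detectable at this depth. With scaling by library size alone the log2 ratio went from -0.26 to 0.096, a shift shared by all genes, whose median went from -0.065 to 0.29. The control level differed between the experiments, at 6.29 CPM in the low NT library against 18.2 and 16.7 CPM in the high NT libraries, or 8.89 against 16.6 and 15.3 CPM with TMM scaling over all 6 libraries. Since the experiments are named after the decrease in Satb1, this decrease is not evidence independent of the labels.

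The high experiment asks which genes differ when Satb1 is strongly reduced in cells that the labels call cancer-associated dendritic cells. Called genes lay in both directions, with single histone and cytokine genes among the falls and single macrophage genes such as Vsig4 and Cd163 among the rises. Among genes with a mean log2 CPM of 1 or more that are not unnamed loci of the kinds left out by the naming rule, the largest falls were in the replication-dependent histone genes Hist1h2ap (-3.42 on the log2 scale), Hist1h2an (-3.07), Hist2h3b (-2.92) and Hist1h3h (-2.59). Also among the 8 largest were Ifnb1, the gene of interferon beta (-2.64), the potassium channel gene Kcna7 (-2.56), s11-6 (-3.17) and Tpt1 (-2.64). The s11-6 and Hist1h2an values varied more between repeats than counting noise allows, with edgeR adjusted p = 0.04997 and 0.03822, and both calls ended when either Satb1 siRNA library was left out (adjusted p = 0.322 and 0.296 for s11-6, 0.289 and 0.285 for Hist1h2an). The s11-6 call also ended with library size alone (adjusted p = 0.0521), without a filter (adjusted p = 0.0551) and with 4 group means over all 6 libraries (adjusted p = 0.0517). Histone and Tpt1 reads can be shared with near-identical copies, so these 5 genes are uncertain. The largest rises were in DQ567786 (1.70), Efhb (1.56), the urea transporter gene Slc14a1 (1.34), the macrophage complement receptor gene Vsig4 (1.30), Gimap4 (1.29), Tmc3 (1.27), the kinase gene Bmx (1.25) and Nhedc2 (1.24). The authors' FPKM of DQ567786 was 0 in every high library, against 153 and 148 in the low NT and low Satb1 siRNA libraries. Its rise is therefore uncertain. Vsig4 stood at 10.4 and 9.62 CPM in the NT libraries and at 24.3 and 25.02 CPM in the Satb1 siRNA libraries. Of 20242 genes tested, 6645 were called higher and 6722 lower at an adjusted p under 0.05 in edgeR, 66.0% in all, and 7690 and 5682 with scaling by library size alone. At least 2-fold changes were seen for 1510 higher and 797 lower genes, and for 56 and 153 of those with a mean log2 CPM of 1 or more. When repeats were summed and the experiment entered as a term, a fit added after seeing the data, edgeR called 6 genes, all lower, and DESeq2 called 85 higher and 135 lower.

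Chemokine and cytokine genes formed the groups with the largest and the third largest median fall. Of 18 chemokine genes, 17 were called lower and 1 higher, 10 of the falls were at least 2-fold, and the median was -1.29. The neutrophil attractants Cxcl1 and Cxcl2 were lower by -1.72 and -1.79, Cxcl2 going from 153 to 44.3 CPM, and the monocyte attractant Ccl2 was lower by -1.27. The abundant Ccl6 was lower by -0.20. The 1 higher gene was Cxcl13, at 0.61. Of 18 inflammatory cytokine genes, 13 were called lower, 1 higher and 4 not, with a median of -0.64. Tnf was lower by -2.06 (33.0 and 32.1 against 8.31 and 7.31 CPM), the interleukin 1 antagonist gene Il1rn by -1.29, Il1b by -1.08 and Il6 by -0.58. Both medians lay at percentile 0 of 10000 random lists matched on mean expression. Limma's camera gave adjusted p = 1.12e-06 for chemokines (adjusted p = 0.250 with an estimated correlation) and adjusted p = 7.24e-04 for cytokines (adjusted p = 0.258 with an estimated correlation). The estimated setting has few residual degrees of freedom here, so a call lost under it does not show that correlation between genes undoes it. In the same libraries the neutrophil marker median was 0.15 and the B cell marker median 0.71. When the 17520 tested genes with a known intron length were ranked by it and cut into 4 equal parts, the part with the longest introns had a median of 0.11 and the part with the shortest -0.096. The nuclear RNAs Malat1, Neat1, Kcnq1ot1 and Xist were called higher, by 0.23, 0.43, 0.51 and 0.039, and Miat was not called (0.31).

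MHC class I and interferon genes were lower as groups, calls that did not hold with an estimated correlation, and the MHC class II list was not called as a group. All 12 genes of MHC class I processing were called lower, with a median of -0.53 (H2-K1 -0.50, the peptide transporter Tap1 -0.75). Of 26 type I interferon response genes 25 were called lower and 1 higher, with a median of -0.42. Rsad2, which encodes the antiviral protein viperin, was lower by -0.81, Ifit2 by -0.58 and Bst2 by -1.08. Of 11 MHC class II genes 7 were called lower, 2 higher and 2 not, with a median of -0.33. H2-Ab1 was lower by -0.87, H2-Aa by -0.61 and the invariant chain gene Cd74 by -0.96. Ciita, the class II transactivator, had a log2 fold change of 0.13 and was not called (edgeR adjusted p = 0.261). Of 10 costimulation genes 7 were called lower, 1 higher and 2 not, with a median of -0.26 (Icosl -0.55, Cd40 -0.23, Cd86 -0.21). Of 19 immunosuppression genes 11 were called lower, 3 higher and 5 not, with a median of -0.16. Within this list the inducible nitric oxide synthase gene Nos2 was lower by -1.74, Cd274, which encodes PD-L1, by -0.72 and galectin-1 (Lgals1) by -0.13, while the scavenger receptor gene Cd163 was higher by 0.98 and the mannose receptor gene Mrc1 by 0.090. Camera's adjusted p was 1.53e-05 for MHC class I (adjusted p = 0.250 with an estimated correlation), 7.37e-09 for interferon (adjusted p = 0.258 with an estimated correlation), 0.0338 for costimulation (adjusted p = 0.302 with an estimated correlation), 0.0104 for immunosuppression (adjusted p = 0.286 with an estimated correlation) and 0.162 for MHC class II. The MHC class II median lay at percentile 0.80 of matched random lists and the costimulation and immunosuppression medians at percentiles 2.84 and 6.84.

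Stress, cell cycle, hypoxia, unfolded protein response, matrix and respiration genes were lower too, with group calls that did not hold with an estimated correlation. All 18 genes of the list of tissue dissociation stress, immediate early and heat shock genes among them, were called lower, with a median of -0.72 (Hspa1a -0.72, Hspa1b -0.55, a pair of near-identical genes whose reads may be shared). Of 24 cell cycle genes 22 were called lower, 1 higher and 1 not, with a median of -0.56, including the proliferation marker Mki67 (-0.59) and topoisomerase gene Top2a (-0.72). Of 18 hypoxia and glycolysis genes 16 were called lower and 2 not, with a median of -0.54 (Ldha -0.65, Eno1 -0.66). Of 15 genes of the unfolded protein response 14 were called lower and 1 not, with a median of -0.47 (Pdia4 -0.86, Pdia6 -0.74). Of 20 matrix and protease genes 14 were called lower, 5 higher and 1 not, with a median of -0.51 (the protease gene Mmp9 0.37). Of 22 mitochondrial respiration genes 18 were called lower, 1 higher and 3 not, with a median of -0.19 (Atp5b -0.37, Atp5a1 -0.19). Camera's adjusted p was 1.03e-07, 1.12e-06, 1.34e-06 and 4.26e-06 for stress, cell cycle, hypoxia and unfolded protein response, and 7.78e-03 and 3.42e-04 for matrix and respiration. For the first 4 and for respiration this became adjusted p = 0.250 with an estimated correlation, and for matrix adjusted p = 0.312 with an estimated correlation.

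In 4 further groups members moved both ways. Of 20 Notch pathway genes 8 were called lower, 3 higher and 9 not (Notch1 -0.44, its ligand gene Jag1 -0.57), and the median was -0.025. Of 20 lipid and cholesterol genes 9 were called lower, 7 higher and 4 not (the lipid droplet gene Plin2 -0.61, the fatty acid carrier gene Fabp4 -0.96), with a median of -0.010. Of 23 ribosomal protein genes 11 were called higher, 9 lower and 3 not (Rpl3 0.20, Rps4x 0.15), with a median of -0.0072. These 3 medians were above 0 with scaling by library size alone, which also put the median of all genes at 0.065, so they stayed below that of all genes. Of 19 complement and phagocytic receptor genes 12 were called lower, 5 higher and 2 not, with a median of -0.22 (C1qb -0.56, Fcgr3 -0.37). Camera called the complement list (adjusted p = 0.0338, adjusted p = 0.537 with an estimated correlation) and none of the other 3 (adjusted p = 0.611 to 0.815).

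**Figure D1:**
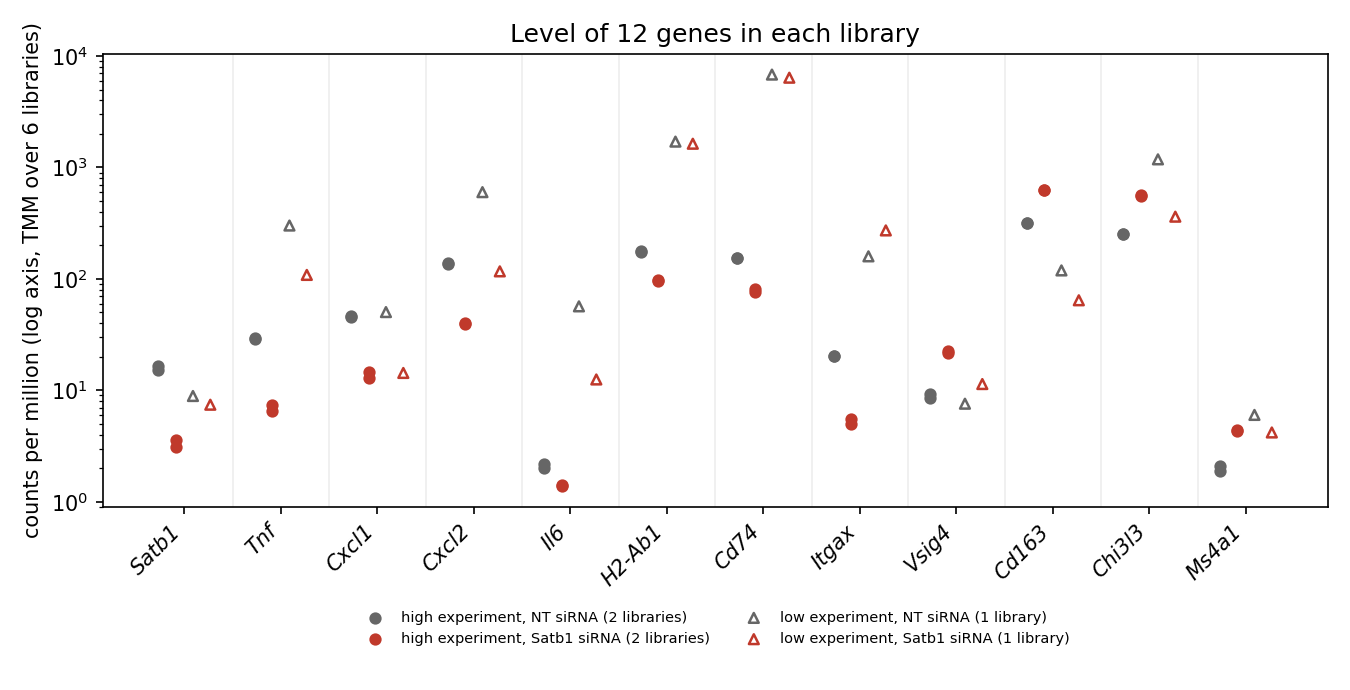
CPM (log axis, TMM scaling over all 6 libraries) of 12 genes in each library; grey marks are NT siRNA, red marks Satb1 siRNA, filled circles the high experiment (2 libraries per siRNA) and open triangles the low experiment (1 library per siRNA). Tnf, Cxcl1, Cxcl2 and Il6 lie lower with Satb1 siRNA in both experiments, Itgax, Cd163, Chi3l3 and Ms4a1 lie in opposite order in the 2 experiments, and Satb1 is clearly lower only in the high experiment (log2 fold change -2.25 against a log2 ratio of -0.26).

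B cell markers were higher as a group in the high Satb1 siRNA libraries, a call that did not hold with an estimated correlation, and the T cell and macrophage lists were not called as groups. Of 12 B cell markers 8 were called higher and 4 not, with a median of 0.71 at percentile 99.95 of matched random lists (Ms4a1 1.15, from 2.09 and 2.33 to 4.88 and 4.97 CPM; Bank1 0.86). Of 20 T cell markers 9 were called higher, 1 lower and 10 not, with a median of 0.41. Cd3d, the gene of a CD3 subunit, was higher by 0.36, and the lower gene was Il7r, at -1.38. With NT siRNA Cd3d stood at 35.8 CPM on average, but Cd3e and Cd3g only at 0.167 and 0.396 CPM, so its level may not reflect T cells. Of 17 macrophage markers 11 were called higher, 5 lower and 1 not, with a median of 0.14 at percentile 99.2, Cd163 going from 355 and 354 to 696 and 701 CPM. Classical dendritic cell markers were split, with 6 of 10 called higher, 3 lower and 1 not, and a median of 0.29. Itgax, which encodes CD11c, was lower by -1.95 (22.6 and 22.5 against 6.13 and 5.53 CPM), while the receptor gene Kit was higher by 0.59. Markers of mature migratory dendritic cells were called lower in 7 of 11 cases, higher in 2 and not in 2, with a median of -0.41 (Marcksl1 -0.41, Relb -0.37). For conventional type 1 dendritic cells 3 of 9 markers were called higher, 4 lower and 2 not (Irf8 -0.27, Wdfy4 0.25). For type 2 and monocyte-derived dendritic cells 3 of 8 were called higher, 4 lower and 1 not (Klf4 0.57, Sirpa -0.23). For plasmacytoid dendritic cells 5 of 9 were called higher, 1 lower and 3 not (Siglech 1.09, Bst2 -1.08).

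Monocyte and neutrophil markers moved in both directions. Of 12 monocyte markers 5 were called higher, 6 lower and 1 not, with a median of -0.037 that was 0.017 with scaling by library size alone, below the median of all genes there (Chi3l3 1.16, F13a1 0.42, Plac8 -1.13). Of 10 neutrophil markers 3 were called higher, 3 lower and 4 not (Cxcr2 0.37, Mmp8 -0.55). Of 6 natural killer cell markers 2 were called higher, 2 lower and 2 not, with a median of -0.21 (Eomes 0.50, Klrk1 0.31). The Klrk1 call ended without NT replicate 1 (edgeR adjusted p = 0.0780) or without Satb1 siRNA replicate 2 (edgeR adjusted p = 0.144), and in DESeq2 (adjusted p = 0.137). Of 16 tumour, epithelial and mesothelial markers 9 were called higher, 2 lower and 5 not, with a median of 0.11 (Wt1 0.54, Gpm6a 0.25). Of 13 fibroblast and endothelial markers 5 were called higher, 5 lower and 3 not, with a median of -0.10 (Dcn 0.32, Vwf -0.63). Of 7 erythroid markers 3 were called higher and 4 not, with a median of 0.20 (Alas2 0.51, Beta-s 0.24). Of the cell marker lists, camera called the B cell list (adjusted p = 5.06e-03, adjusted p = 0.258 with an estimated correlation) and the list of mature migratory dendritic cells (adjusted p = 0.0294, adjusted p = 0.302 with an estimated correlation). Its adjusted p was 0.0514 for T cells and 0.171 for macrophages. The mean and the median differed in sign for classical dendritic cells (-0.085 and 0.29), type 2 dendritic cells (0.16 and -0.082) and neutrophils (-0.0035 and 0.15). Camera called 15 of the 31 lists in all. With an estimated correlation it called 0, with 4 lists at an unadjusted p under 0.05, while fry called 24. Correlation alone does not account for this loss. The cell cycle list had an estimated correlation of -0.042, below the preset 0.01, and still went from camera p = 1.09e-07 to p = 0.0276 (both unadjusted). Adjusted over the list alone, the number of members called was the same as over all genes tested for 29 lists; it was 9 in place of 11 for Notch and 21 in place of 20 for ribosomal proteins.

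**Figure D2:**
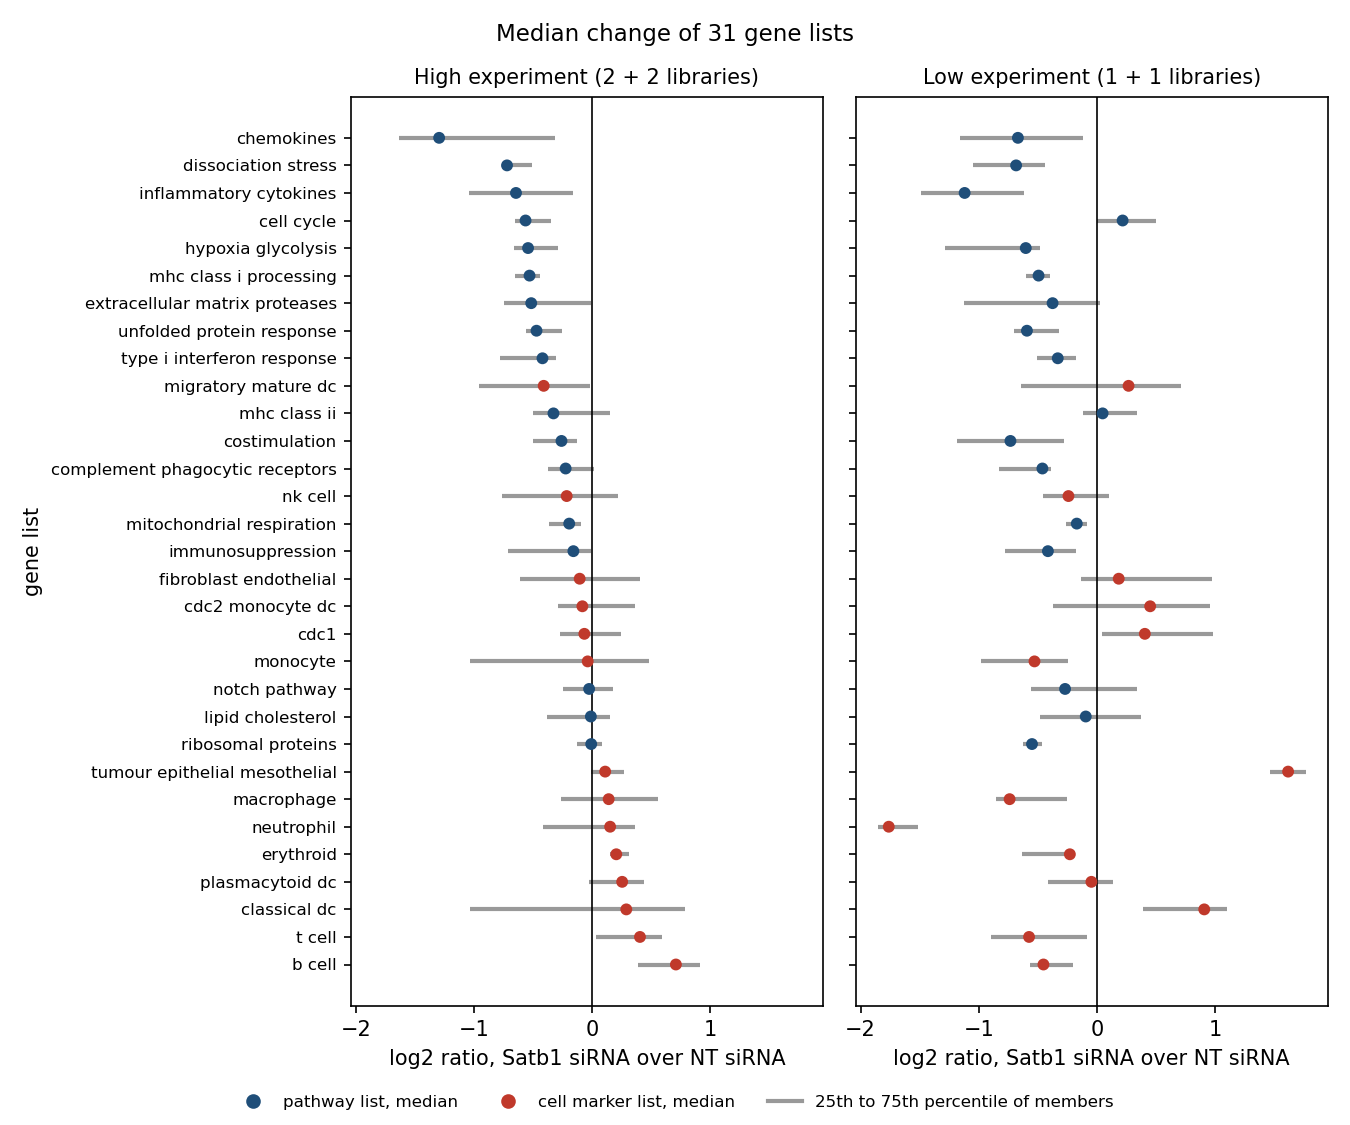
Median log2 ratio of Satb1 siRNA over NT siRNA (points; blue, pathway lists; red, cell marker lists) and the range from the 25th to the 75th percentile of members (bars) for the 31 gene lists fixed beforehand, in the high experiment (left) and the low experiment (right). Chemokines have medians of -1.29 and -0.67, and the neutrophil (0.15 and -1.76) and tumour, epithelial and mesothelial lists (0.11 and 1.62) stand far apart between the experiments.

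In the low experiment cytokine and chemokine genes were again lower in the Satb1 siRNA library, and neutrophil markers were lower with them. With 1 library per siRNA there is no replicate check and no p-value, and the values describe these libraries. Of 15 expressed cytokine genes 13 were lower and 9 of them at least 2-fold, with a median of -1.12. Il6 went from 56.7 to 12.5 CPM (-2.18) and Tnf from 301 to 109 CPM (-1.47). Of 18 chemokine genes 14 were lower, 6 at least 2-fold, with a median of -0.67, and Cxcl2 went from 600.2 to 117 CPM (-2.36). Costimulation genes had a median of -0.73 (Cd40 -1.24, from 377 to 159 CPM), stress genes -0.68 (Hspa1a -2.93), hypoxia and glycolysis -0.60, unfolded protein response -0.59, MHC class I -0.49 and immunosuppression -0.41. MHC class II genes were near 0, with a median of 0.048 that was -0.013 with DESeq2 size factors (H2-Ab1 -0.063, Cd74 -0.093), while Ciita was higher by 0.99. Lgals1 was higher by 0.66, from 388 to 614 CPM. Cell cycle genes were higher, with a median of 0.22. The remaining pathway medians were -0.55 for ribosomal proteins, -0.46 for complement, -0.38 for matrix and proteases, -0.33 for interferon, -0.27 for Notch, -0.17 for mitochondrial respiration and -0.094 for lipids, and of these interferon, Notch, respiration and lipids were above 0 with scaling by library size alone. Over 12977 expressed genes 1055 were at least 2-fold higher and 436 at least 2-fold lower. The split was 1598 to 164 with scaling by library size alone, which moved the median of all genes from -0.065 to 0.29.

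The cell markers of the low experiment moved apart. All 12 expressed neutrophil markers were lower, 10 of them at least 2-fold, with a median of -1.76 (S100a8 from 87.7 to 24.3 CPM, S100a9 from 130 to 35.4 CPM). All 14 expressed tumour, epithelial and mesothelial markers were higher, 12 at least 2-fold, with a median of 1.62 (Wt1 from 37.6 to 143 CPM, Upk3b from 40.1 to 198 CPM). The medians lay at percentiles 0 and 100 of 10000 matched random lists. Macrophage markers had a median of -0.74, monocyte markers -0.53, T cell markers -0.57 and B cell markers -0.45. Classical dendritic cell markers had a median of 0.91 (Itgax 0.77, Flt3 1.34), type 1 and type 2 dendritic cells 0.41 and 0.45, mature migratory dendritic cells 0.27 and fibroblast and endothelial markers 0.18. The fibroblast and endothelial median lay at percentile 75.4 of matched random lists, and the monocyte median at percentile 4.54. Plasmacytoid dendritic cell, natural killer cell and erythroid markers had medians of -0.046, -0.24 and -0.23, each above 0 with scaling by library size alone.

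Genes called in the high experiment tended to move the same way in the low experiment. Of 5722 genes called lower and expressed in the low experiment 4064 were lower there too (71.0%), and of 3754 called higher 2279 were higher (60.7%), where 44.1% of all expressed genes were above 0. The medians were -0.20 and 0.14, at percentiles 0 and 100 of 10000 matched random lists. At least 2-fold lower levels in both experiments were seen for 36 genes, where independent lists would share 6.22, and at least 2-fold higher levels for 23, where they would share 6.77. These expected values take no account of expression level, so they do not show an excess over genes of similar expression. Ccl5, Cxcl10, Il1b, Nos2, Ptgs2 and Tnfaip3 were among the 36. Among called genes of at least 2-fold, 62.8% of the lower and 55.4% of the higher ones kept their sign, and the median of the higher ones lay at percentile 45.7. Across 12920 genes, which are not independent replicates, the changes of the 2 experiments had a Spearman correlation of 0.32. The experiments share no control library. In the low experiment neutrophil markers were lower (median -1.76) and tumour, epithelial and mesothelial markers higher (median 1.62). How the shared changes relate to these markers was not tested.

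The size of the change differed between the libraries of the experiments by more than the spread between repeats for many genes. An interaction test in edgeR over all 6 libraries called 8267 of 18413 genes, 4392 with a higher and 3875 with a lower log2 change in the low experiment. The genes with the smallest p included the lysozyme genes Lyz2 (0.60 in the high and -1.12 in the low experiment) and Lyz1 (0.54 and -1.07), which may share reads. F13a1 (0.42 and -1.01) and Chi3l3 (1.16 and -1.71) also moved in opposite directions. Slfn4 was lower mainly in the high experiment (-1.54 and -0.084), and Saa3 mainly in the low experiment (-0.33 and -2.19). Rsad2 (-0.81 and -1.33), Ccl6 (-0.20 and -0.68), Ctsb (-0.35 and -0.63) and Ctsc (-0.16 and -0.90) were lower in both. The spread in this test comes from the repeats of the high experiment alone, and the lone libraries are assumed to vary like them. Noise of library preparation may be missing from that spread. The low libraries also nearly lacked transcripts without a poly(A) tail, a difference that this test does not measure. DESeq2 called 3634 genes, 1328 higher and 2306 lower, and with DESeq2 size factors edgeR called 3626 higher and 4704 lower, so which direction held more genes depended on the scaling.

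The control libraries already differed between the experiments. Antigen presentation genes and classical dendritic cell and neutrophil markers were higher in the low NT library than in the high NT libraries, with medians of 3.32 on the log2 scale for MHC class II, 2.84 for MHC class I, 3.16 for classical dendritic cell markers and 4.44 for neutrophil markers. Inflammatory cytokine, chemokine, interferon response and monocyte lists were higher as well (medians of 2.78, 2.32, 3.10 and 2.47, each at percentile 100 of matched random lists). The medians for plasmacytoid and type 2 dendritic cells, 0.19 and 1.01, lay at percentiles 66.96 and 89.42 of matched random lists. Cd74 stood at 6811 CPM in the low NT library and at 172 CPM on average in the high NT libraries, each scaled within its own fit. Tumour, epithelial and mesothelial markers were lower in the low NT library, with a median of -1.46. Transcripts that lack a poly(A) tail were nearly missing from the low libraries. A set of 27 such transcripts summed to 18730 and 18650 CPM in the high NT libraries, 19250 and 19310 CPM in the high Satb1 siRNA libraries, and 3.18 and 9.53 CPM in the low NT and low Satb1 siRNA libraries, although the labels name the same total RNA kit for all. This set includes histone genes, whose messages lack the tail. Hist1h2ap, Hist1h2an and Hist2h3b had 0 counts in both low libraries, which allows up to 0.111 CPM with NT and 0.122 CPM with Satb1 siRNA. Of 13595 genes 3521 were at least 2-fold higher and 3034 at least 2-fold lower in the low NT library, 48.2% together. With scaling by library size alone the split was 1962 to 4928.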

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

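Of the tests in this part, the one on intron length and the count of other splits of the libraries were set before their results were seen, and the tests on repeat libraries, cell markers, Satb1 level and RNA without a poly(A) tail were chosen afterwards.

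The interaction test called 8267 genes, but it takes its spread from the near-identical repeats of the high experiment only. The count therefore measures differences beyond the spread of those repeats, which may hold no noise of library preparation, and is no test of the conditions. Of the named genes with a mean log2 CPM of 0 or more in the low experiment, 7 moved by at least 1.5-fold in opposite directions. These single differences were not tested over independent samples of the low experiment, which has 1 library per siRNA. Gimap4, the B cell gene Bank1, the macrophage gene Cd163, the monocyte gene Chi3l3 and Lyz2 were higher with Satb1 siRNA in the high experiment (1.29, 0.86, 0.98, 1.16 and 0.60) and lower in the low one (-0.65, -0.72, -0.89, -1.71 and -1.12). Itgax, which encodes CD11c, went from -1.95 in the high to 0.77 in the low experiment, and s11-6, whose repeats disagreed, from -3.17 to 2.85.

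The repeats of the high experiment were almost the same in most genes, and differed at 59 genes for NT and 89 for Satb1 siRNA. Repeat sequencing of a single RNA preparation needs a biological coefficient of variation near 0, and the value was 0.00988, so this is a candidate explanation. A chi-square per gene of 1.202 and 1.370 also lies close to that of counting noise. No biological explanation was tested, since the labels name no mice or pools, and very similar pooled samples stay open. With the repeats summed and the experiment as a term, edgeR called 6 genes and DESeq2 85 higher and 135 lower, against 13367 in edgeR with the repeats as separate libraries.

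Cytokine and chemokine genes were lower with Satb1 siRNA in both experiments, with medians over both lists of -0.73 and -0.79. The list of tissue dissociation stress was lower by a similar amount (medians of -0.72 and -0.68), and whether handling of the cells differed was not tested. Random lists matched on intron length and expression served to test a larger share of nuclear or unspliced RNA in the high experiment. The median of the cytokine and chemokine genes lay at percentile 0 of 10000 such lists (95% of lists from -0.27 to 0.018). They fell more than genes of similar intron length and expression. The change followed intron length only weakly (Spearman correlation 0.18 across genes). Matching on it therefore cannot decide whether a larger nuclear share was the cause. Malat1, Neat1 and Kcnq1ot1, which are nuclear, were higher (0.23, 0.43 and 0.51), so that such a share may still contribute. Fewer neutrophils are argued against only weakly there. The median of their markers was 0.15, above that of the cytokine genes by more than the interquartile range of 0.79, a rule set afterwards. Their mean was -0.0035, 3 of 10 were called higher, 3 lower and 4 not, and some had low levels (Lcn2 1.04 CPM with NT), so the list is a weak guide. Monocyte markers went both ways (median -0.037, interquartile range 1.51), so fewer monocytes and lower expression in them cannot be told apart. In the low experiment fewer neutrophils may contribute to the lower values, as their markers had a median of -1.76 (S100a9 from 130 to 35.4 CPM, the more abundant Csf3r from 274 to 174 CPM). The labels describe no sort against them. Their share of the RNA is not known. Whether their loss could lower more abundant genes such as Cxcl10 (from 2658 to 864 CPM) was not tested. Macrophage markers (median -0.74, 13 of 17 below 0) and monocyte markers (median -0.53, 11 of 12 below 0) were lower there too. Fewer cells of any of these kinds, and lower expression in them, cannot be told apart. A common effect through Satb1 is a hypothesis that stays open, since the interval of the Satb1 ratio in the low experiment starts at 0.670 and includes 1.

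The control libraries of the experiments differed widely. RNA without a poly(A) tail may have been kept in the high experiment and lost in the low one, since the median of 21 such transcripts was -7.82 (low over high control, log2). Another make-up of cells may contribute. MHC class II genes, which do have the tail, had a median of 3.32 at percentile 100 of matched random lists. The chemokine, interferon response and monocyte lists also lay at percentile 100, so this value cannot separate cell make-up from other differences between the experiments. Both explanations stay open together, as each needs only part of the genes. The labels name the same kit and cell type for all, and a biological difference between the experiments was not tested.

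An effect of Satb1 siRNA common to all 6 libraries, with the experiment as a term in edgeR, was called for 3163 genes over the sequenced libraries, and for 6 in edgeR with repeats summed (DESeq2, 85 higher and 135 lower), where each group counts as 1 sample. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many, and the highest of the others gave 0 (3128 genes at an unadjusted p under 0.05). That split swaps the low libraries and is the only other one that keeps repeats together; the rest put near-identical repeats on opposite sides and say little, so 2 splits are informative. Even with 10 splits the share cannot fall under 0.05.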

How the results depend on the processing

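The fits with repeats summed, the limit of at least 2-fold, TMM over the low pair alone and the random lists as a test of list medians were chosen after seeing the data; the other alternatives were planned.

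The count of 13367 genes called in the high experiment stayed within 1.5 times under other scalings, tools, filters, thresholds and gene sets (10099 with the DESeq2 Wald test to 14391 without a filter), and between 11942 and 12092 when any library was left out. It was 2307 with at least 2-fold changes, 3163 with all 6 libraries and the experiment as a term, and 6 with the repeats summed as well (1633 of 19068 at an unadjusted p under 0.05; DESeq2 called 85 higher and 135 lower). The fits with the experiment as a term ask for a common effect; the cause was not tested. In them Satb1 had log2 fold changes of -1.64 (adjusted p = 0.0568) and -1.28 (adjusted p = 0.618) in edgeR; it was called in every other fit, at -2.35 to -2.15. The 6 genes were Mt2, Cxcl2, Cxcl1, Procr, Tnf and AK199495, the last with 0 counts in the low libraries.

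Named genes that were called took the opposite sign only in these fits, which take in the low libraries, where each of them moved the other way. With all 6 libraries and with repeats summed, in turn, they were Lgals1 0.14 and 0.27, Mrc1 -0.046 and -0.12, Rpl3 -0.011 and -0.13, Rps4x -0.071 and -0.20, F13a1 -0.040 and -0.29, and Beta-s -0.19 and -0.43. With repeats summed alone, they were Mmp9 -0.12, Chi3l3 -0.27, Cxcr2 -0.013, Lyz2 -0.26 and Lyz1 -0.26. Of the 88 named genes tested besides Satb1, 48 and 74 kept their sign and lost their call in the 2 fits, where the reversed ones lost theirs too, and 3 (s11-6, Hist1h2an, Klrk1) under another setting. For type 2 dendritic cells (median -0.082) fry gave the opposite direction to camera; the cause was not tested.

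Camera called 14 to 16 lists when a library was left out, 0 with an estimated correlation and 24 with fry. Satb1 in the low experiment was 0.096 with library size alone, which moved all genes alike. The interaction gave 8067 to 8178 genes without any 1 library and 3634 with DESeq2. The share of called genes with the same sign in the low experiment, 66.9%, was 68.0% with DESeq2 size factors, 70.0% for DESeq2 calls, 60.6% for changes of at least 2-fold and 67.9% to 68.3% with a library left out; the cause was not tested. Total counts of 2-fold genes in the low experiment and between controls stayed within 1.5 times, but with library size alone higher and lower genes went from 1055 and 436 to 1598 and 164, and from 3521 and 3034 to 1962 and 4928. The replicate numbers did not pair samples (correlation of deviations -0.041), and the fit with replicate number as a block called 13248 genes and 16 lists. A fit for normalized values was not run, because counts were given. Genes under 0.122 CPM are within the limit of a count of 0 in the low experiment.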

Other observations

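All genes in this part were chosen after their values were seen. The 36 genes at least 2-fold lower with Satb1 siRNA in both experiments included Nos2, the inducible nitric oxide synthase, with log2 ratios of -1.74 in the high and -3.48 in the low experiment, and the prostaglandin synthase gene Ptgs2 (-1.20 and -2.25). They also included Irg1, whose product makes itaconate (-1.41 and -1.82), and the pattern recognition receptor gene Clec4e (-1.04 and -3.004). The metallothionein gene Mt2 (-1.63 and -1.93), the protein C receptor gene Procr (-1.48 and -1.63), the thrombospondin gene Thbs1 (-1.09 and -1.14) and the ferritin light chain gene Ftl1 (-1.02 and -1.03) had similar ratios in both.

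Spp1, the gene of osteopontin, was lower in the high experiment (-1.78) and higher in the low one (0.56). Gata6, a transcription factor of resident peritoneal macrophages, was higher in both (0.56 and 1.79). In the low experiment the macrophage list that holds it had a median of -0.74, and the tumour, epithelial and mesothelial list 1.62. Which cells the Gata6 rise came from was not tested. In the low experiment the elastin gene Eln (2.74) and Sparc (2.14) were higher, beside the tumour, epithelial and mesothelial markers. The acute phase gene Saa3 and the antiprotease gene Slpi were lower there (-2.19 and -2.53), beside the neutrophil markers. Of 55 histone genes with a mean log2 CPM of 0 or more, 53 were called lower in the high experiment and 24 were at least 2-fold lower, with a median of -0.96. In the low experiment their median ratio was 0, where 27 transcripts without a poly(A) tail, histone genes among them, summed to only 3.18 and 9.53 CPM.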
